A study of Homo sapiens with 2 samples.

How the data were processed

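Gene expression was measured by RNA sequencing in 2 libraries of the human neuroblastoma line SH-SY5Y, 1 from cells stably transfected with an empty vector and 1 from cells stably transfected with a pancEts-1 expression vector. Per the labels' protocols, stable cells were selected with neomycin, RNA was taken with Trizol, and libraries were made with Illumina's TruSeq RNA kit, which does not mark the strand of the transcript. Per the series' design text, paired reads of 100 bp came from an Illumina instrument, and HTSeq 0.6.0 counted the reads of each gene. Bowtie2 2.0.6, TopHat2 2.0.9 and the genome build hg38 are named in the submitters' processing notes. The annotation release, the choice of rows and the scaling between libraries are not given in the sources used here.

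The deposited values are a signal per Ensembl gene rather than whole counts. Each library's values are whole multiples of 1 step, 0.99274 for the empty vector library and 1.00731 for the pancEts-1 library, and genes without reads hold 1.39e-17 in place of 0. Dividing by the step returned whole reads for 100% of the values, within 0.01 reads. The recovered reads came to 17994357 and 20136986. The factors implied by the steps are 1.0656 and 0.93844, equal to the TMM factors that edgeR gives for the recovered reads to all the digits shown, so the signal is treated here as counts scaled by TMM. The smallest total of any row over the 2 libraries was 2 reads, found in 2510 rows.

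The design written before the data were examined assumed whole counts. Because the values are scaled, the ratio of each gene is instead the log2 of the deposited value of the pancEts-1 library over that of the empty vector library, with a pseudocount of 0.5 added to each, which understates the ratios of low genes. Levels are given as CPM, the deposited value per 1000000 of a common library size of 19035549, the geometric mean of both libraries' scaled sizes. The 95% intervals are exact conditional binomial (Clopper-Pearson) intervals on the recovered reads, were added after the unit was known, and cover counting error only, without the pseudocount. A gene with 0 reads in a library was set against a floor of 3 reads there, and its ratio is a bound. The 95% interval of such a gene reaches somewhat nearer 0 than this bound. With 1 library per group there is no replicate error, no test between conditions and no p-value.

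Genes with a mean CPM of at least 1 over both libraries were compared. A gene was counted as higher or lower when its ratio was at least 2-fold and its interval lay off 0. The interval condition left the counts of the compared genes unchanged. Counts under other settings and calls in simulated data used the ratio alone, unless an interval is named. Gene lists fixed before the data were examined were summarised by the median log2 ratio of their measured members, with members at 0 entering at their bound. Each median is given as a percentile among medians of 10000 random lists of protein-coding genes, of the same size and matched on mean expression in 20 bins. The same was done for the genes of each chromosome. The alternatives described below drew fewer random lists than this, so their percentiles are less exact. That matters most for lists near the edge of a range. A percentile describes these 2 libraries and tests nothing about the conditions.

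The named genes follow a rule fixed before the data were examined. It takes ETS1, CTNNB1, HNRNPK, MYC, MYCN, CCND1 and any noncoding gene overlapping or starting within 10 kb of a transcription start of ETS1. It adds the 12 highest and 12 lowest protein-coding genes and the 4 highest and 4 lowest noncoding genes with a mean CPM of at least 5, ranked by the interval bound nearest 0. From each list it takes the 2 highest and 2 lowest members, of which those within 1.5-fold may be left out. Some genes that the rule takes are not reported here. Genes outside the rule are said to be chosen after their values were seen.

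Positions and gene types come from GENCODE release 29 on GRCh38, the assembly that hg38 names. It holds 27152 of the 27612 listed identifiers, and the other 460 hold 0.0838% of the reads. Symbols come from a separate table of current gene names, which held 26979 of them, and otherwise from GENCODE. The authors' release can differ, so a symbol can stand for a slightly different gene model.

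The alternatives were DESeq2 size factors, total counts, upper quartile factors, other filters on expression, other fold thresholds, a prior count of 2, removal of trends with expression, GC content and length, random lists from all genes, lists without shared members, and ratios of recovered reads without a pseudocount. The last, and the 2-fold count on recovered reads, were chosen after the unit was known. Leaving out a replicate was not possible. Factors came from R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and the rest from Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

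The steps were tested on simulated data, drawn for the 14628 compared genes from the libraries' own means and depths with 200 genes given known ratios for the pancEts-1 library against the empty vector library. Of 100 genes simulated 8-fold apart, 100 were called beyond 2-fold, and of 100 simulated 2.83-fold apart, 98 were. Counting noise alone put 22 unchanged genes beyond 2-fold. The intervals held the true ratio for 95.5% of genes, and 3 of 100 lists without a shift fell outside the central 95% of random lists. Those lists were themselves drawn at random from the same genes, and the simulation held no variation between cultures. The rate therefore checks the steps only. It says nothing about the fixed lists, whose members can vary together.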

Results

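RNA sequencing compared 2 stable derivatives of SH-SY5Y, an established human neuroblastoma cell line, at passages 15 to 18. One carried an empty vector and the other an expression vector for pancEts-1, a noncoding RNA from the promoter region of ETS1, the gene of a transcription factor. Each group held 1 library. The recovered reads came to 17994357 in the empty vector library and 20136986 in the pancEts-1 library, over 27612 listed genes, of which 26027 and 25374 had at least 1 read. A count of 0 allowed a level of up to 0.156 CPM in the empty vector library and 0.159 CPM in the pancEts-1 library. Because each group has 1 library, no difference reported here has a replicate check, and each compares these libraries rather than the conditions. Intervals are at the 95% level and cover counting error only, and log2 ratios are pancEts-1 over empty vector.

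The first question was whether the pancEts-1 library carried more RNA from the ETS1 promoter region. ETS1-AS1 (ENSG00000254588), an antisense gene at chromosome 11, 128526142 to 128530389 on the plus strand of GRCh38, had 0 reads in the empty vector library and 12756 reads in the pancEts-1 library. That is 675 CPM, at least 4314-fold higher. It was the only annotated noncoding gene that the rule found at the ETS1 starts, and it lies inside ETS1 (ENSG00000134954), which spans 128458761 to 128587558 on the minus strand. The labels do not say which sequence was cloned, so ETS1-AS1 is not shown to be the vector's insert. The kit does not mark strand, so strand cannot separate its reads from reads of ETS1 where the genes overlap. In the empty vector library ETS1 had 777 reads and ETS1-AS1 had 0. At that level, ETS1 left no counted reads on ETS1-AS1. ETS1 itself stood at 40.5 CPM in the empty vector library and 48.9 CPM in the pancEts-1 library, a log2 ratio of 0.27 (interval 0.13 to 0.41).

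The other genes fixed in advance were CTNNB1, HNRNPK and genes of growth control. CTNNB1, the gene of beta-catenin, stood at 400 and 607 CPM in the empty vector and pancEts-1 libraries, a log2 ratio of 0.60 (0.56 to 0.64). HNRNPK, an RNA-binding protein, had a log2 ratio of 0.47 (0.44 to 0.50). CCND1, the G1 cyclin D1, had a log2 ratio of 0.29 (0.21 to 0.37), and MYC, a growth-promoting transcription factor, -0.29 (-0.35 to -0.22). MYCN, the neuroblastoma oncogene, had 5 reads and 6 reads, too few to show a difference. No member of this group differed by 2-fold.

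Across the 14628 genes with a mean CPM of at least 1, 2207 genes (15.1%) were at least 2-fold higher in the pancEts-1 library and 2132 genes (14.6%) at least 2-fold lower. The split depends on the scaling: with total counts it was 1760 higher and 2678 lower. Total counts moved the median log2 ratio of all genes by -0.18 and upper quartile factors by -0.11, so list medians below are set against random lists under the same scaling. Under the authors' scaling 49.9% of genes lay within 1.5-fold. Protein-coding genes gave 1901 higher and 1558 lower of 12358, and the other gene types 306 higher and 574 lower of 2270. At 32-fold or more, 194 genes were higher and 93 were lower. The spread of ratios far exceeded counting error: between 20 and 100 CPM the robust SD of the log2 ratio was 0.69, against a median interval half-width of 0.15.

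**Figure D1:**
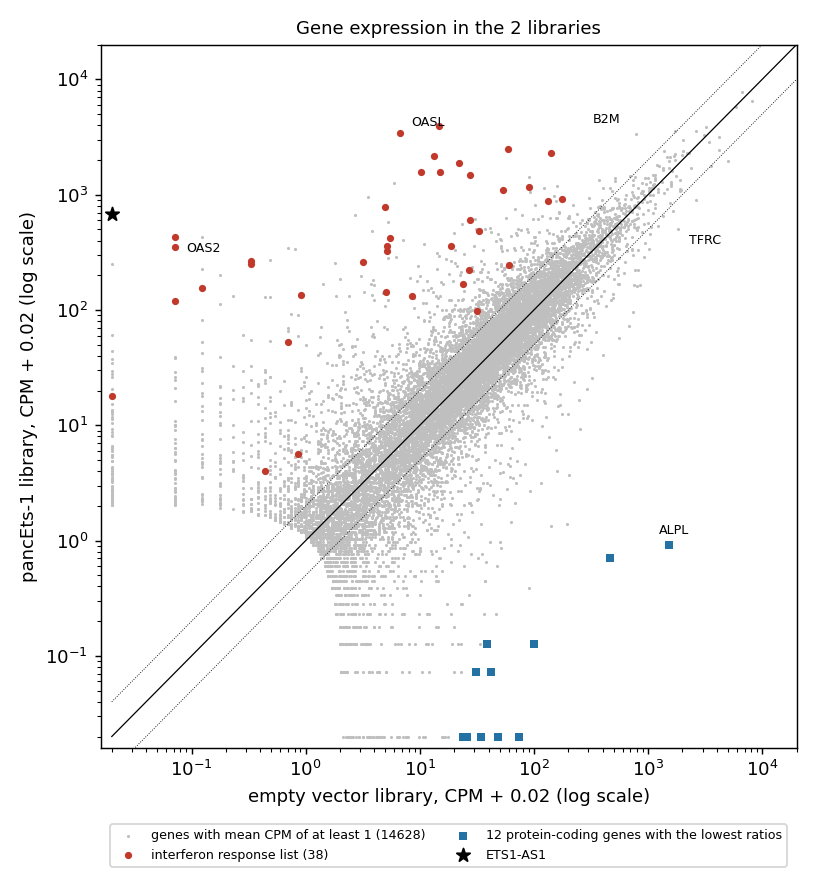
Level of each of the 14628 compared genes in the empty vector library (x axis) and the pancEts-1 library (y axis), in CPM plus 0.02 on log scales; the solid line marks equal levels and the dotted lines 2-fold. The 38 interferon response genes lie above the upper dotted line, ETS1-AS1 sits at 0 reads on the x axis, and ALPL is far below the lines.

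Interferon response genes held the highest ratios. Of the 12 highest protein-coding genes, 7 were members of the fixed list of 38 interferon response genes. OAS2, an antiviral oligoadenylate synthetase, had 1 read in the empty vector library and 8075 reads in the pancEts-1 library, a log2 ratio of 12.41 (10.52 to 18.30). OASL stood at 6.68 and 3434 CPM, 512-fold higher, with a log2 interval of 8.76 to 9.27. IFI44L had 1 read and 6680 reads, and TRIM22 and RSAD2, a restriction factor and the antiviral enzyme viperin, had log2 ratios of 9.62 and 9.51. IFITM1 and CXCL10, a membrane restriction factor and a chemokine, had log2 ratios of 10.21 and 10.58. All 38 list members were at least 2-fold higher in the pancEts-1 library, the lowest being IFIT5 at 1.62 and IFITM2 at 2.00. The list's median was 6.04, or 66.0-fold, above all 10000 matched random lists, and its summed level was 1026 CPM against 31278 CPM.

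The other 5 of the 12 included SLC1A3, GBP1, UBE2L6 and CXCL11. SLC1A3, a glutamate transporter, had 0 reads and 4690 reads, at least 1586-fold higher. GBP1, a guanylate-binding protein, had 1 read and 6611 reads (log2 ratio 12.12, interval 10.23 to 18.02). UBE2L6, the conjugating enzyme for ISG15, had a log2 ratio of 10.78 (9.25 to 14.15), and the chemokine CXCL11 one of 10.10 (8.77 to 12.60).

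Genes of MHC class I antigen presentation were also higher. All 15 measured members were at least 2-fold higher, with a median of 3.03 (8.15-fold), above all 10000 random lists. HLA-F stood at 1.36 and 71.9 CPM, a log2 ratio of 5.70, and the immunoproteasome subunit PSMB9 at 3.23 and 144 CPM, a log2 ratio of 5.46. The lowest was the peptide-loading protein TAPBP at 1.64. Reads of HLA genes can be split among near-identical copies, so the values of single HLA genes are uncertain. Leukocyte markers were low in both libraries: of 17 markers listed, 11 had a row and 3 had a mean CPM of at least 1. PTPRC, the pan-leukocyte antigen CD45, chosen after its values were seen, had 4 reads and 5 reads. LCP1, an actin-bundling protein on that list, had 4 reads and 321 reads.

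Immediate-early and AP-1 genes, which respond to growth factor and stress signals, formed the next group. Of 30 measured members, 25 were at least 2-fold higher in the pancEts-1 library and 0 were lower, with a median of 2.30 (4.91-fold), above all 10000 random lists. SPRY4 and DUSP4, feedback inhibitors of MAP kinase signalling, had log2 ratios of 5.73 and 4.51. Of the 30, 6 genes belong also to another list. ETS family transcription factors had a median of 0.83 at the 99.93 percentile, with 9 of 19 higher and 0 lower. ETV7 had 0 reads and 258 reads, and the epithelial factor EHF had a log2 ratio of 4.23. GABPA was the lowest at -0.93.

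**Figure D2:**
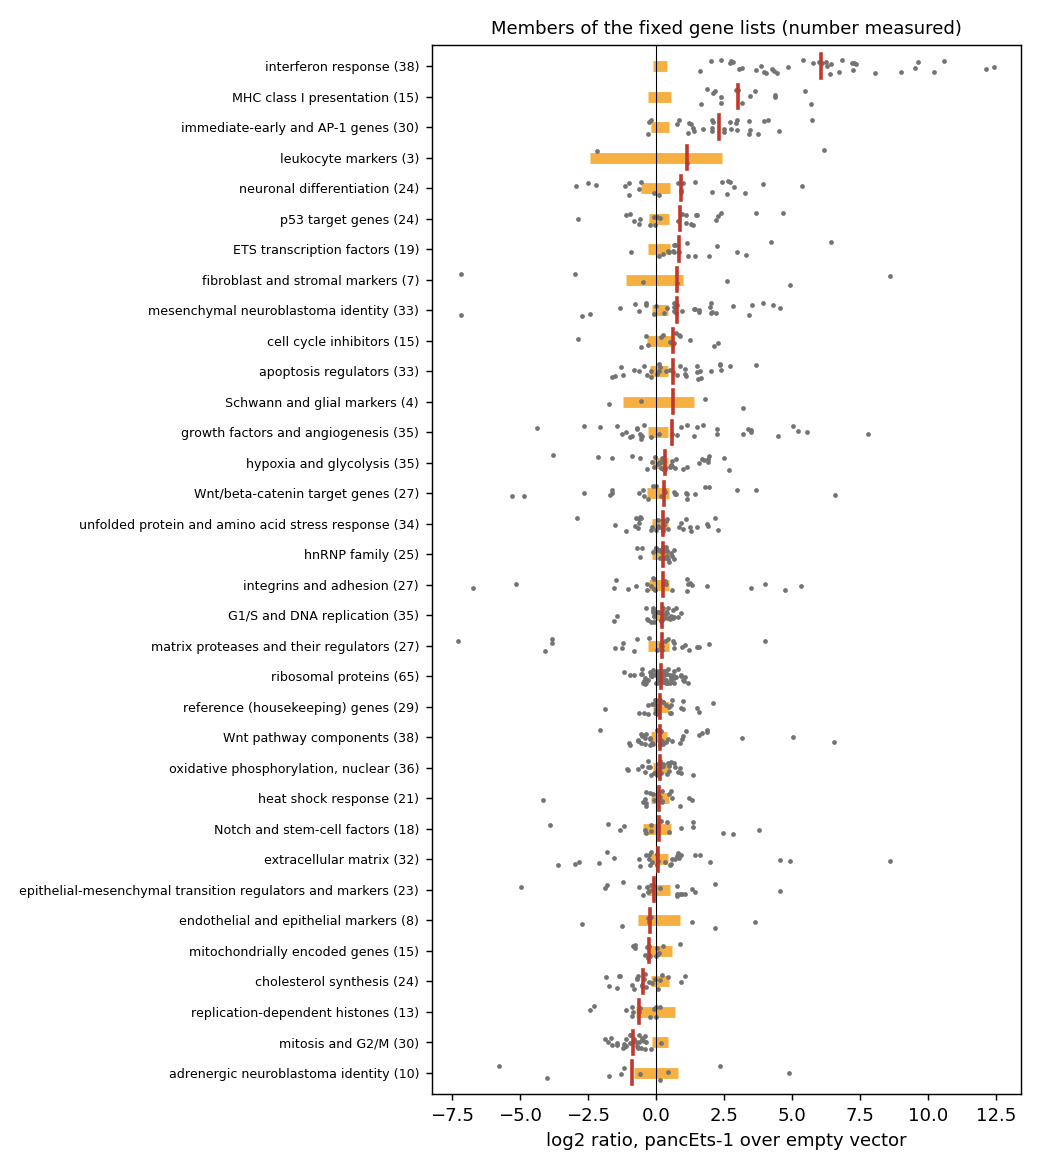
Log2 ratio, pancEts-1 over empty vector, of each measured member of the 34 fixed gene lists (grey points), with the list median (red bar) and the central 95% of medians of matched random lists (orange band). The interferon response, MHC class I and immediate-early lists lie to the right of their bands at medians of 6.04, 3.03 and 2.30, and the mitosis list lies to the left at -0.86.

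Genes of mitosis and cholesterol synthesis were lower in the pancEts-1 library. In the mitosis and G2/M list, 29 of 30 members had a ratio below 0 and 12 were at least 2-fold lower, with a median of -0.86 (1.81-fold lower), below all 10000 random lists. The kinesin CENPE stood at 90.9 and 24.8 CPM, a log2 ratio of -1.87, and HMMR, a spindle protein, had one of -1.79. Genes of G1/S and DNA replication did not stand apart, with a median of 0.21 at the 63.1 percentile. In that list CDK6, a G1 kinase, had a log2 ratio of -1.55, and the helicase subunit MCM5 and the factor E2F2 ones of 0.92 and 0.82. Replication-dependent histone genes had a median of -0.64 at the 4.06 percentile, with H3C10 at -2.43 and H2AC11 at -2.28. Cholesterol synthesis genes had a median of -0.49 (1.40-fold lower), with 5 of 24 at least 2-fold lower and 1 higher, and 2 of 10000 random lists lay as far from the random median. The enzymes DHCR7 and MVK had log2 ratios of -1.83 and -1.75, while STARD4, in cholesterol transport, had one of 0.90.

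Inhibitors of the cell cycle, p53 targets and apoptosis regulators had medians above those of random lists, some of which depended on the settings. CDKN1A, the cyclin-dependent kinase inhibitor p21, stood at 51.8 and 251 CPM (log2 ratio 2.28, interval 2.18 to 2.38), and CDKN1C, the inhibitor p57, had a log2 ratio of 2.14. RBL2, a relative of the retinoblastoma protein, had a log2 ratio of -0.57. The cell cycle inhibitors had a median of 0.63 at the 98.6 percentile, with 3 of 15 higher and 1 lower. That place was lost at much the same size without the gene shared with another list, with a median of 0.57 at the 96.4 percentile. That place was also lost, narrowly, after removing the trend with expression (0.52, 97.3 percentile) or with GC content and length (0.60, 97.2 percentile). The p53 targets had a median of 0.89, with 11 of 24 higher and 2 lower, above 99.99% of random lists. Without the 5 targets that other lists share, the median was 0.14 at the 56.6 percentile. TP53INP1 and PMAIP1, p53-inducible genes of autophagy and apoptosis, had log2 ratios of 4.68 and 3.66, and ZMAT3 and DDB2 ones of -2.88 and -1.09. The apoptosis regulators had a median of 0.62 at the 99.8 percentile, with 14 of 33 higher and 4 lower. The pore-forming BAK1 had a log2 ratio of 2.70, the inhibitor BIRC5 one of -1.63 and the BH3-only gene BMF one of -1.51.

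For the Wnt pathway, which beta-catenin serves, neither list stood apart from random lists. The Wnt/beta-catenin targets had a median of 0.29 at the 86.9 percentile, with 9 of 27 higher and 6 lower. The membrane protease MMP14 and the Wnt inhibitor RNF43 had log2 ratios of 6.58 and 3.67, and the feedback inhibitors NKD2 and AXIN2 ones of -5.30 and -4.87. The pathway components had a median of 0.15 at the 59.7 percentile, with 8 of 38 higher and 1 lower. The receptor FZD4 and the factor TCF7L1 had log2 ratios of 6.53 and 5.04, and the receptor FZD6 one of -2.07. FZD2, another receptor, stood at 33.8 and 16.9 CPM. None of the 25 genes of the hnRNP family, nuclear RNA-binding proteins, differed by 2-fold. Their median was 0.25 at the 66.5 percentile, and they ran from PCBP1 and HNRNPC at 0.66 and 0.65 to HNRNPH2 and HNRNPF at -0.58 and -0.72.

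Genes of neuroblastoma cell states were mixed. Of 36 noradrenergic identity genes, 20 had a row in the tables analysed here and 10 had a mean CPM of at least 1. TH and DBH, enzymes of noradrenaline synthesis chosen after their values were seen, had 1 read and 1 read, and 2 reads and 0 reads. The 10 measured members had a median of -0.88 at the 1.68 percentile, which was lost without the expression filter, with 20 genes at a median of 0.01, and narrowly after removing trends with GC content and length, with a median of -0.78 at the 2.75 percentile. GCH1, an enzyme of cofactor synthesis for TH, had a log2 ratio of 4.88 and TBX2 one of 2.36, while DACH1 had one of -5.78 and LMO1 had 49 reads and 0 reads. The mesenchymal identity genes had a median of 0.76 at the 99.96 percentile, with 15 of 33 higher and 4 lower. Without members shared with another list the median over 18 genes was 1.26. FN1, the matrix protein fibronectin, stood at 23.5 and 558 CPM (log2 ratio 4.57). PDGFRB, a growth factor receptor, had 369 reads and 2 reads, and MEOX1 a log2 ratio of -2.72. Of 49 neuronal differentiation genes, 39 had a row and 24 had a mean CPM of at least 1. Median levels of the 24 were low, 3.57 CPM in the empty vector library and 6.32 CPM in the pancEts-1 library. Their median log2 ratio was 0.92 at the 99.97 percentile, with 10 of 24 higher and 5 lower. Without the expression filter the median over 39 genes was 0.38 at the 98.98 percentile. The neurofilament NEFH had 0 reads and 121 reads and UCHL1 a log2 ratio of 3.94, while the neuronal tubulin TUBB3 and SEMA3C had ones of -2.94 and -2.51. Of Notch and stem-cell factors, 5 of 18 were higher and 4 lower, with a median of 0.12 at the 62.2 percentile. Their extremes were DLL1 at 3.78, NES at 2.81, HEY2 at -1.76 and HES6, which had 45 reads and 0 reads and lies in the run on chromosome 2 described last.

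Adhesion, matrix and growth factor genes held large ratios in both directions. Growth factors and angiogenesis genes had a median of 0.57 at the 99.7 percentile, with 15 of 35 higher and 6 lower. That place was lost without shared members, with a median of 0.34 at the 92.3 percentile, and without the expression filter, at the 36.0 percentile. FGF13 had 0 reads and 657 reads and ANGPTL4 a log2 ratio of 5.54, against -4.39 for FGFR2 and -2.64 for BMP4. Integrins and adhesion genes gave 10 of 27 higher and 5 lower (median 0.25, 76.6 percentile). PCDH17 had 1 read and 59 reads (log2 ratio 5.33, interval 3.37 to 11.23) and CNTN1 had 1 read and 39 reads (4.74, 2.74 to 10.65). CADM1 had 379 reads and 3 reads (-6.74, -9.24 to -5.40) and CHL1 had 54 reads and 1 read (-5.17, -11.06 to -3.19). Matrix proteases gave 6 of 27 higher and 7 lower (median 0.21, 71.5 percentile), from the urokinase receptor PLAUR at 4.02 and MMP19 at 1.94 to PLAU, the urokinase itself, at -4.07 and ADAM12 at -7.27. Extracellular matrix genes gave 6 of 32 higher and 6 lower (median 0.06, 31.9 percentile). LUM had 0 reads and 1143 reads and COL3A1 a log2 ratio of 4.92, while NID2 and DCN had ones of -3.62 and -2.99. The regulators and markers of epithelial-mesenchymal transition gave 5 of 23 higher and 4 lower (median -0.06, 22.4 percentile). With a mean CPM of at least 5 their median was 0.76, at the 99.8 percentile. The epithelial genes EPCAM and CLDN7 had log2 ratios of 2.15 and -4.98, and FOXC2 one of -1.90.

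The hypoxia, stress, ribosomal, nuclear oxidative phosphorylation and reference lists lay inside the central 95% of random lists. Hypoxia and glycolysis genes had a median of 0.33 at the 89.3 percentile, with SLC2A3 at 2.69, PFKFB4 at 2.49, CA9 at -2.12 and CA12 at -3.79. Unfolded protein and amino acid stress genes had a median of 0.26, with CEBPB at 2.29, CHAC1 at 2.18, SLC7A11 at -1.52 and the serine synthesis enzyme PHGDH at -2.90. Heat shock genes had a median of 0.12, with DNAJA1 at 1.34, HSPE1 at 1.20 and CRYAB at -4.16. Ribosomal protein genes had a median of 0.16, with RPL13 at -1.18, and ribosomal protein genes have many pseudogenes that can take their reads. Nuclear oxidative phosphorylation genes had a median of 0.14, with COX6A1 at 1.36 and NDUFA10 at -1.05. Reference genes had a median of 0.16, with B2M, the MHC class I light chain, at 2.10, EMC7 at 1.59 and TFRC, the transferrin receptor, at -1.86. With total counts the medians of the heat shock, ribosomal, oxidative phosphorylation, reference, Wnt component, integrin, extracellular matrix and Notch lists lay below 0, so no direction is given for these lists. Mitochondrially encoded genes had a median of -0.25 at the 2.24 percentile and 0 of 15 differed by 2-fold, with MT-RNR1 at 0.88 and MT-CYB at -0.84. Their place was lost after removing the trend with expression, with a median of -0.30 at the 5.28 percentile, and after removing trends with GC content and length, with one of -0.13 at the 5.48 percentile.

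Few markers of other cell types were measured, and their ratios were mixed. Schwann and glial markers had 4 measured members, with ERBB3 at 3.19, PMP22 at 1.78 and MBP at -1.73. Fibroblast and stromal markers had 7, of which 3 were higher and 2 lower, LUM and COL3A1 against PDGFRB and DCN. Endothelial and epithelial markers had 8, with CDH5 at 3.64, VWF at -2.74 and ESAM at -1.24. Leukocyte markers had 3, among them CSF1R at -2.18. Summed over its measured members, the endothelial and epithelial list stood at 2076 CPM in the empty vector library and 1976 CPM in the pancEts-1 library. The Schwann, fibroblast and leukocyte lists summed to 83.9, 78.7 and 4.48 CPM in the empty vector library. In the pancEts-1 library they summed to 180, 157 and 22.9 CPM. The medians of these lists, 0.61, 0.77, -0.21 and 1.13, lay within the central 95% of random lists of their sizes. With a mean CPM of at least 5, the Schwann list's 3 genes had a median of 1.78 at the 99.1 percentile and the fibroblast list's 4 genes one of -1.11 at the 1.55 percentile.

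Ranked by the interval bound nearest 0, the lowest protein-coding genes began with alkaline phosphatases. ALPL, the tissue-nonspecific enzyme, had 29501 reads in the empty vector library and 17 reads in the pancEts-1 library, 1539 against 0.900 CPM (log2 ratio -10.70, interval -11.52 to -10.06). ALPI, the intestinal enzyme, had 8974 reads and 13 reads, but it shares near-identical sequence with ALPP and ALPG, so its value is uncertain. QPRT, an enzyme of NAD synthesis, had 1938 reads and 2 reads (-9.58, -12.95 to -8.04). TOGARAM2 had 1420 reads and 0 reads, at least 466-fold lower, and C5AR2, a complement receptor, had 936 reads and 0 reads, at least 307-fold lower. PASD1 and CPVL, with 662 reads and 493 reads in the empty vector library, also had 0. ALPK2 had 804 reads and 1 read (-9.05, -14.94 to -7.15), IGFN1 592 reads and 1 read, and NDUFA4L2 741 reads and 2 reads. Also among the 12 are ASB1 and TRAF3IP1, neighbours on chromosome 2. Among noncoding genes, TP73-AS1 had 2 reads and 558 reads, the pseudogene HLA-K 0 reads and 249 reads, and AL445490.1 2 reads and 441 reads. The lowest were LINC00942 with 676 reads and 0 reads, AC097478.1 with 1729 reads and 7 reads, MIR3667HG with 205 reads and 0 reads, and FENDRR with 996 reads and 16 reads. Antisense and overlapping genes among these cannot be told from their partners without strand.

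By chromosome, medians of 18 of the 23 chromosomes compared lay outside the central 95% of matched random lists, 8 above and 10 below. Neighbouring genes are not independent, so these ranges are too narrow. Chromosome 5 had the highest median, 0.30 over 678 genes, and chromosome 19 followed at 0.29 over 1005 genes. Chromosome 17 had the lowest, -0.23 over 916 genes, and chromosome 10 followed at -0.22 over 567 genes. Without the expression filter, 12 of the 18 stayed outside that range, and the medians of chromosomes 5, 19, 17 and 10 were 0.080, 0.091, -0.16 and -0.16.

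**Figure D3:**
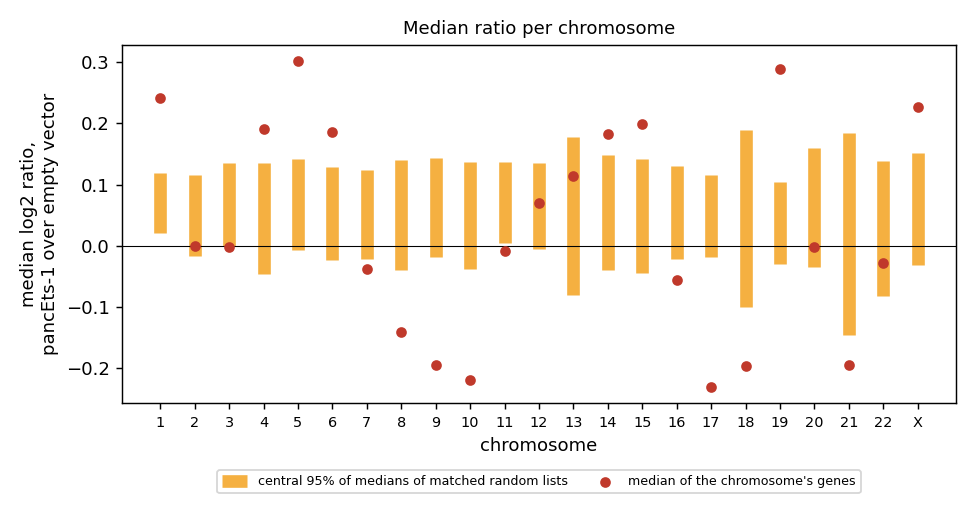
Median log2 ratio, pancEts-1 over empty vector, of the compared genes of each chromosome (red points), with the central 95% of medians of matched random lists (orange bars). Chromosomes 5 and 19 lie above their bars at 0.30 and 0.29, and chromosomes 17 and 10 below at -0.23 and -0.22.

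ASB1, TRAF3IP1 and HES6 belong to a run of 8 consecutive expressed protein-coding genes on chromosome 2, from 237966827 to 238452250, each at least 4-fold lower in the pancEts-1 library. This run and the neighbouring genes named below were singled out after the values were seen. The 8 genes together had 2068 reads in the empty vector library and 5 reads in the pancEts-1 library. TRAF3IP1, a ciliary transport gene, had 597 reads and 1 read (log2 ratio -8.62, interval -14.51 to -6.72), ASB1 454 reads and 0 reads, ILKAP 379 reads and 1 read, and the clock gene PER2 246 reads and 2 reads. KLHL30 had 201 reads and 1 read, and UBE2F, SCLY and HES6 had 85 reads, 61 reads and 45 reads against 0. On either side, RBM44 had 20 reads and 17 reads and TWIST2 191 reads and 168 reads. Farther out, LRRFIP1 and HDAC4 had log2 ratios of -1.22 and -1.78, and RAB17 had 121 reads and 0 reads.

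**Figure D4:**
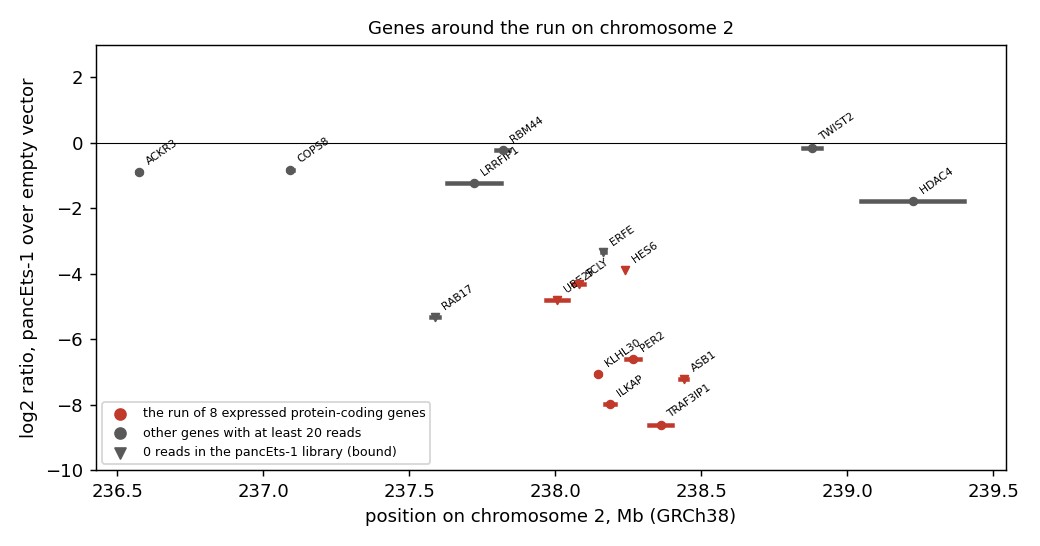
Log2 ratio, pancEts-1 over empty vector, of genes with at least 20 reads in total, against position on chromosome 2 in Mb (GRCh38); bars show each gene's span, red marks the run of 8 genes and triangles mark bounds from 0 reads. The run lies between RBM44 at -0.21 and TWIST2 at -0.16.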

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

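The alternatives on recovered reads were chosen after the unit was known, and the others before the data were examined. The count of higher genes, 2207, became 3917 without an expression filter, 3810 at 1.5-fold and 884 at 4-fold. The count of lower genes, 2132, became 4807, 3522 and 785 under those settings, 1188 with a mean CPM of at least 5, and 1409 with the whole interval beyond 2-fold. These shifts follow from testing more or fewer genes or from a different threshold. Recovered reads without a pseudocount gave 2219 higher and 2145 lower.

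Relative to matched random lists, the medians of the 14 lists outside the central 95% of random lists kept their direction in all settings run but 2. Without an expression filter the noradrenergic list went from -0.88 to 0.0076 and the growth factor list from 0.49 to -0.016. The ETS family list, at 0.73, became 0.59 without the filter and 0.87 without shared members. The p53 list, at 0.77, became 0.028 without shared members, and the immediate-early list, at 2.16, became 1.93 without the filter, 1.96 with a mean CPM of at least 5 and 2.38 without shared members. The neuronal list, at 0.96, became 0.38 without the filter and 0.79 after removing the trend with expression. The mesenchymal list, at 0.62, became 1.12 without shared members. With a mean CPM of at least 5 the growth factor list became 0.71 and the apoptosis list, at 0.50, became 0.73, and without shared members the growth factor list became 0.26. The mitochondrially encoded list, at -0.43, became -0.40 with a mean CPM of at least 5, -0.35 after removing the trend with expression and -0.34 after removing trends with GC content and length. The cause was not tested. Of these 14 lists, among 34, 9 lay outside that range under each of the 11 alternatives run for them. Of the 23 chromosome medians, relative to matched random lists, 17 moved without the expression filter and 0 moved under the other settings run. Among single named genes, 683 values stayed within their counting interval and 132 moved beyond it. Reversal was scored only for genes at least 2-fold apart, and 0 values reversed. Total counts, the scaling farthest from the authors', moved the median log2 ratio by -0.18, too little to reverse such genes. Smaller ratios could change sign and were not scored for it. Counting depth limits low genes most: between 1 and 5 CPM the median interval half-width was 0.73.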

Other observations

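All tests in this part were chosen after the results were seen, as were the genes named in it that the rule does not take. Several interferon genes had reads in the pancEts-1 library alone. IFNB1, the gene of interferon beta, had 0 reads and 198 reads in the empty vector and pancEts-1 libraries. Against the floor of 3 reads, IFNB1 was at least 67.0-fold higher. IFNL1, a type III interferon, had 0 reads and 349 reads. IFNL2 and IFNL3, which are near-identical and can share reads, had 151 reads and 224 reads against 0. The chemokine CCL5 had 9 reads and 5120 reads, the cytokine IL6 9 reads and 2445 reads, and CXCL8 3 reads and 290 reads (log2 ratio 6.39, interval 5.05 to 8.90). The log2 ratio was 4.99 for the RNA sensor TLR3 and 5.54 for the adaptor STING1. CD274, the gene of the immune checkpoint ligand PD-L1, had a log2 ratio of 4.59.

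ALPG, the germ cell alkaline phosphatase, ran opposite to ALPL and ALPI, with 113 reads and 23744 reads (log2 ratio 7.73). ALPP, the placental enzyme, had 7456 reads and 7347 reads. These paralogs can share reads.

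The first pattern weighed is the higher level of interferon response genes in the pancEts-1 library. Scaling between the libraries is argued against, since the lowest median log2 ratio of that list over 4 scalings was 5.86. Leukocytes in the culture would bring their abundant transcripts, but the median of the 11 leukocyte markers with a row was 0.212 CPM in the pancEts-1 library, with PTPRC at 0.265 CPM, LYZ at 0.106 CPM and LCP1, the highest, at 17.0 CPM. A response to pancEts-1 RNA remains a hypothesis. It cannot be told apart from a difference between the 2 stable lines or their cultures other than the pancEts-1 RNA, such as a response to transfection or the selection of different clones, because there was 1 pancEts-1 library.

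The second pattern is the run of 8 genes on chromosome 2 with almost no reads in the pancEts-1 library. Chance placement is argued against: 0 of 1000 shuffled orders of the 12345 expressed protein-coding genes, of which 575 were at least 4-fold lower, gave a run as long, and the longest shuffled run was 5 genes. Identifiers missing from the counting of the pancEts-1 library would leave 0 reads throughout, but 4 of the 8 genes had 1 or more. Loss of DNA in the pancEts-1 line stays open: the 3 other genes of the span that overlap none of the 8 had 49 reads and 2 reads, or 4.14% of their scaled reads (interval 0.488% to 15.8%), which is too few to decide. Silencing of the region was not tested, and neither can be told apart from the other without DNA data.

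The third pattern is that TH, DBH and part of the other noradrenergic neuroblastoma genes were near 0 in both libraries. Depth is argued against, since 0 reads allow at most 0.159 CPM in either library. Of the 20 listed genes with a row, 6 reached 10 CPM in either library, among them GCH1, GATA2 and KLF13. That number does not decide whether these were cells of another identity or state than the label's neuroblastoma line, which may differ in these genes, and it cannot be told apart here from a loss of noradrenergic expression in culture.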
